A study of Naumovozyma castellii with 2 samples.

How the data were processed

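Each library was deposited as a list of distinct 36-nt reads with the count of each read, 1 list per genotype. The counts in the deposited files are whole numbers of reads and are not normalized. The deposited lists hold 2 further columns with no header, of the kind other: the third marks the reads that hold the start of the adapter, which was checked on every read and had 0 exceptions, and the fourth is a smaller count, never above the read count, whose filter is not given in the sources used here. Per the labels' protocols, the libraries were made from poly(A) RNA of log-phase cells, and the design text says that they hold RNAs with a 5' monophosphate. The software that made the lists is not given in the sources used here.

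The reads used hold an insert of 20 or 21 nt followed by a 12-nt adapter sequence, which was found exactly and without an unread base in the insert in 26.6% of reads with AGO1 and 21.7% without. The most abundant inserts are the reverse complements of the mature 18S, 25S and 5.8S rRNA 5' ends, with the RNA's 5' end next to the adapter. A site was therefore the first 20 nt of the RNA, read as the reverse complement of the 20 insert bases next to the adapter, and position 1 is its first base. Before the data were examined the site had been defined as the first 20 nt of the listed sequence, and the orientation was changed once the rRNA ends were seen. A usable tag had the exact adapter at the end of a 20- or 21-nt insert and no unread base in the insert. All other reads were left out, 53.3% of reads with AGO1 and 55.9% without holding at least 1 unread base anywhere. Of the usable tags, 49.8% with AGO1 and 52.6% without had a 20-nt insert. There were 1316604 distinct sites with AGO1 and 712403 without. RPM values are usable tags scaled to 1000000 per library.

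The main rules were fixed before the data were examined. A site was enriched with at least 20 tags in the higher library and at least 10 times the RPM of the lower one, counts under 3 in the lower library being set to 3. Ratios carry exact conditional binomial 95% intervals and shares exact Clopper-Pearson 95% intervals. PCR copies are not independent molecules, so intervals and floors cover counting error only. Shares at each position were set against 10000 random lists matched on total count, as a description of these libraries. The named sites were the 10 AGO1-enriched sites with the most AGO1-library tags and the 5 Δago1-enriched sites with the most Δago1-library tags, and the named loci were the 10 with the most AGO1-library tags in enriched sites. Loci were to be sites merged by genome position, and assembled stretches took their place after the data were seen. Error variants took 9 of the 10 and 4 of the 5 sites named in this way, so the rule was applied again without them.

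The other choices were made after the data were seen. A site was an error variant when it had 1 mismatch from a site at least 5 times as abundant over both libraries, or 2 or 3 mismatches, or an inner insertion or deletion of 1 nt, from a site at least 20 times as abundant. Opposite-strand tags of a site were those overlapping it by at least 17 nt, and 3 or more in the AGO1 library were required. Stretches were extended from each site through overlapping 15-mers of both libraries and strands, each seen at least 2 times, stopping where the next base was not at least 5 times as frequent as its rival. They are short assemblies and have no coordinates. Stretches that shared at least 14 nt end to end, on either strand, were also counted as joined. The rRNA ends, the resistance genes and the protein segments they were compared with were written from general knowledge and not taken from a reference, so the rRNA and marker identities rest on those sequences. A frame was called similar to a protein at a local alignment score of at least 60 (Biopython). A stretch without such similarity can still code for a protein that was not among the segments compared. Protein similarity does not name the gene, and no gene names are given for tags.

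No genome was used here, and a table of locus tags without sequence cannot place a tag. Matching to the genome was therefore replaced by the adapter rule, and the annotation classes by rRNA matches. The location of sites, sense and antisense tags per gene, positions along genes and the gene lists were not analysed here. The check of the deleted genes was replaced by the resistance genes.

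The alternatives changed the scaling, the tag length, the minimum count, the fold, the depth of the AGO1 library and the merging of neighbouring 5' ends. Those added after the data were seen used the reads of the fourth column, allowed 1 mismatch in the adapter, and applied another error variant rule. The site rule was tested on simulated counts for 36867 sites made from the real means and library sizes. It called 1 of 50 sites changed 5-fold, 28 of 50 changed 10-fold, 49 of 50 changed 20-fold and 50 of 50 changed 40-fold, and 0 of 36667 unchanged sites in either direction. The changed sites were drawn only from the more abundant sites, so these recoveries do not carry over to sites with few tags. The error variant rule marked 20 of 20 simulated variants and 0 of 200 random sequences. The simulated variants lay well inside the rule's own limits, so this shows only that the rule runs as written. How it treats real sites near those limits was not tested. The simulation held counting error only. The software was Python 3.11.15, numpy 2.4.6, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.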

Results

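The data are 5' ends of RNAs from Naumovozyma castellii (the labels use its older name, Saccharomyces castellii), a budding yeast that has an Argonaute protein, which Saccharomyces cerevisiae has lost. The libraries were made from poly(A) RNA, and the design text says that they hold RNAs with a 5' monophosphate. The tags do not show whether each RNA had a poly(A) tail. The downstream piece of a cleaved mRNA has both a 5' monophosphate and a poly(A) tail. Both strains lacked XRN1, the main cytoplasmic exonuclease that degrades such pieces from their 5' end. There were 2 libraries, 1 for each genotype. The Δxrn1 strain kept AGO1 (the AGO1 library), and the Δxrn1 Δago1 strain also lacked AGO1 (the Δago1 library). Cells were grown at 25 °C to an OD600 of 0.6, and 5 µg of poly(A) RNA was used. The AGO1 library held 11971056 reads and the Δago1 library 9653986. Of these, 3181864 reads (26.6%) and 2097617 reads (21.7%) gave a usable tag, a read whose insert ended in the exact adapter and held no unread base. The AGO1 library was thus 1.52 times as deep. With 1 library per genotype there is no replicate check and no test between genotypes. All intervals are exact 95% intervals for counting error only, and the comparisons are between these libraries.

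The first question was what the monophosphorylated RNA captured from poly(A) RNA consisted of with and without AGO1. The most abundant 5' ends in both libraries were those of mature ribosomal RNA, which together made up 16.3% of tags in the AGO1 library (16.3 to 16.4) and 20.9% in the Δago1 library (20.8 to 20.9). The 18S rRNA end, TATCTGGTTGATCCTGCCAG, gave 274612 tags with AGO1 and 238582 without. The 25S end, TTGACCTCAAATCAGGTAGG, gave 158415 and 138620, and the 5.8S end, AAACTTTCAACAACGGATCT, gave 86890 and 60995. The longer form of 5.8S rRNA, which starts 6 or 7 nt upstream, made up 4.94% of both 5.8S forms with AGO1 (4.81 to 5.07) and 5.82% without (5.66 to 5.99). A further 7.55% and 8.78% of tags lay within 3 mismatches of one of these ends.

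Ribosomal RNA fragments with 5' ends inside the assembled parts of the mature molecules were far more frequent in the AGO1 library. Inner rRNA below means these parts only, and rRNA outside them was not recognised. They made up 0.503% of its tags (0.495 to 0.511) and 0.108% of the tags of the Δago1 library (0.104 to 0.113), a 4.64-fold difference (4.44 to 4.85). The ratio was 4.56 (4.28 to 4.85) in the assembled part of 18S rRNA. In the 2 assembled parts of 25S rRNA it was 4.07 (3.63 to 4.59) and 5.03 (4.66 to 5.42). The short part of 5.8S rRNA had only 27 tags against 8, a ratio of 2.22 (0.983 to 5.67) whose interval spans 1. Over 207 single sites inside rRNA the median ratio was 4.61, with a 5th percentile of 1.30 and a 95th percentile of 8.73. The libraries therefore differed in their content of inner rRNA fragments, and with 1 library per genotype this cannot be told apart from the loss of AGO1. Inner fragments of other RNAs were not measured as a class, and only a kanamycin resistance gene, described below, was split into its start and inner part. The difference bears on how every ratio below is read. The remaining tags, 75.6% with AGO1 and 70.2% without, were not placed in an annotation class and can include rRNA outside the assembled parts.

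The next question, the stated purpose of the pair of libraries, was which 5' ends depended on AGO1. A site, defined as the first 20 nt of the RNA, was called enriched when it had at least 20 tags in one library and at least 10 times the RPM (usable tags scaled to 1000000 per library) of the other. Counts under 3 in the lower library were set to 3. By this rule 202 sites were higher in the AGO1 library and 108 in the Δago1 library. The directions had unlike cut-offs, since the AGO1 library was deeper. The smallest count that passed was 46 tags (14.5 RPM) in the AGO1 library and 20 tags (9.53 RPM) in the Δago1 library. With the AGO1 library thinned to the other's depth, 207 and 75 sites passed. Scaled by the median of site ratios, the same rule gave 377 and 75. Of the 202 sites, 77 differed from a far more abundant site by at most 3 mismatches or an inner insertion or deletion of 1 nt, the form a misread base takes, and 64 of those 77 were within 3 mismatches of a mature rRNA end. Of the 108 sites, 98 were of this form. Without such error variants, 125 sites were higher in the AGO1 library and 10 in the Δago1 library, or 244 and 5 with median scaling. Of the 10 sites, 3 belonged to a hygromycin resistance gene with no tags in the AGO1 library. This filter was chosen after the data were seen. The 125 sites held 11046 tags with AGO1 and 107 without, and 71 of them had no tags at all in the Δago1 library. The assembled parts of inner rRNA accounted for 9 of the 125, which is a minimum for rRNA.

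**Figure D1:**
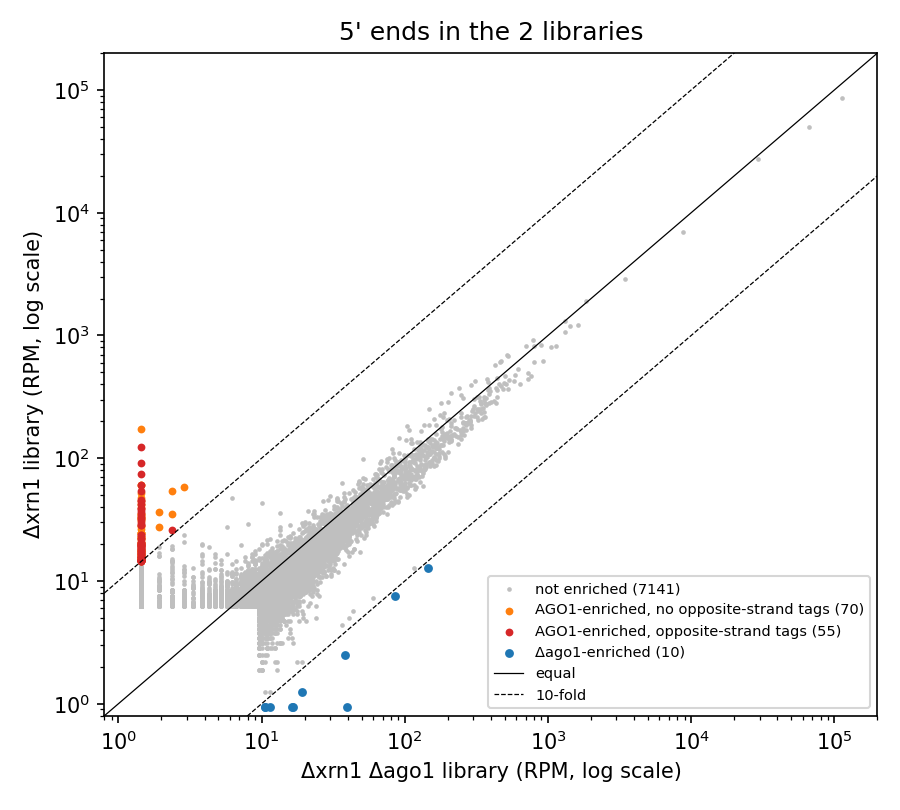
Each point is a 20-nt site with at least 20 tags in a library, error variants left out, placed by its RPM in the Δxrn1 Δago1 library (horizontal, log scale) and the Δxrn1 library (vertical, log scale), with counts under 3 drawn at 3. The 125 AGO1-enriched sites (55 with and 70 without opposite-strand tags) lie above the upper dashed 10-fold line, the 10 Δago1-enriched sites below the lower one, and 7141 sites are in neither class.

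The site with the most AGO1 tags once error variants were left out was AAGTCTTGATCAAGCAAGTT, with 546 tags against 3, a ratio of 120 (40.8 to 584). TAATACTGTAGTGCCAATTC followed with 391 tags against 0, which is at least 85.9-fold higher at a floor of 3 tags (exact lower bound of the ratio 69.5). TACTGTAGTGCCAATTCCAA had 292 tags against 1 and CATGCCAATTAAGGATGAGA 237 against 2. TCCAAAGTTGAAAATCCTGC and AGTATAGTAAACCGTTTTGT each had 192 against 0, at least 42.2-fold higher (lower bound 34.0). TGATAGGGTGTTCAACGAGG had 191 against 0, at least 42.0-fold higher (lower bound 33.8). Its whole assembled stretch had 327 tags against 1, so an origin in the deleted AGO1 gene itself stays open for this site. GAAAATCCTGCCTTTCAAGG had 171 against 2. The other 2 of the 10 named sites kept a few tags without AGO1. AGGTAACGTTTGTGGTGACT had 186 against 6, a ratio of 20.4 (9.21 to 56.4), and AGGCTTTGACCAGAGGTGAA had 172 against 5, a ratio of 22.7 (9.53 to 70.7). Had error variants been kept, 9 of the 10 named sites would have been variants of an rRNA end.

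Of the 5 named sites higher in the Δago1 library, 4 lay in a single assembled stretch of 51 nt, and GAGGAGAACAATTGTTCTCC shared an 18-nt palindrome with it. TGTTCTCCAGTACACTAGAT had 304 tags without AGO1 against 41 with it, or 145 against 12.9 RPM. ATTGTTCTCCAGTACACTAG had 180 against 24, GAGAACAATTGTTCTCCAGT 83 against 3, GAGGAGAACAATTGTTCTCC 80 against 8, and AGAACAATTGTTCTCCAGTA 40 against 4.

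Many AGO1-enriched sites lay in RNAs read from both strands. Of the 125 sites, 55 (44.0%, 35.1 to 53.2) overlapped at least 3 AGO1-library tags on the opposite strand, against 262 of 7141 sites that were not enriched (3.67%, 3.24 to 4.13). Random lists of 125 sites matched on total count held a median of 2 such sites and at most 7 in 10000 draws. The interval and the draws treat sites as independent, which the enriched sites are not. The 7141 sites, from which matched lists were drawn, are not free of sites higher with AGO1. A site with under 46 AGO1-library tags could not pass even with 0 tags in the other library. Over all 7276 sites, error variants left out, the 95th percentile of the log2 ratio was 4.03, which is above 10-fold. This holds for every contrast with sites not enriched below. Of the 55 sites, 18 lay in 1 assembled stretch, and 1 site per joined stretch leaves 14. In the Δago1 library, 13 of the 125 sites (10.4%) had at least 3 opposite-strand tags, against 142 of the 7141 (1.99%), so the share was also higher beside the enriched sites without AGO1. Taken over all 125 sites, each opposite-strand tag counted once and enriched sites left out, the opposite-strand tags numbered 1155 with AGO1 and 78 without, a ratio of 9.76 (7.76 to 12.4). Beside the 7141 sites not enriched they numbered 6453 and 3529, a ratio of 1.21 (1.16 to 1.26). The 70 other sites are described as lacking opposite-strand tags.

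Joining overlapping tags around the 125 sites gave 41 stretches of sequence, from 21 to 756 nt long with a median of 117 nt, which held 123 of the sites. There were 5 pairs of stretches that shared at least 14 nt end to end, so the 41 stretches are not all separate RNAs, and joining these pairs left 36. On 13 of them at least 5% of the AGO1-library tags, and at least 10 tags, lay on the strand with fewer enriched sites or none, and these held 58 sites. On 11 of the 13, the interval of the ratio lay above 1 on both strands. These strand totals include the enriched sites, which were chosen for a high ratio, so the ratios on their strands are raised by that choice. Outside the enriched sites, the ratio over both strands went from 2.95 to 26.8 with a median of 10.1. Inner rRNA had a ratio of 4.64, so a ratio above 1 does not set a stretch apart from it. The ratio on the strand with more enriched sites went from 3.24 to 66.2. On 9 of the 13 stretches the other strand held no enriched site, and its ratio there went from 0.758 to 24.2 with a median of 3.64. The other 4 had enriched sites on both strands. The richest stretch was 165 nt long and held 18 enriched sites, with 3413 tags against 34 on 1 strand (ratio 66.2, 47.3 to 95.7) and 217 against 42 on the other (3.41, 2.44 to 4.86). A 169-nt stretch had 1410 tags against 40 on 1 strand (23.2, 17 to 32.7) and 796 against 42 on the other (12.5, 9.16 to 17.5). An 80-nt stretch, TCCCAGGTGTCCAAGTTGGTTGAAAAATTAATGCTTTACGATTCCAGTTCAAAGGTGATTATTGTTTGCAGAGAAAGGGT, had nearly equal tags on both strands, 672 against 25 (17.7, 11.9 to 27.6) and 566 against 20 (18.7, 12 to 30.8). A 155-nt stretch with the single site of 546 tags, which also held a reading frame similar to an abundant yeast protein, had 760 against 49 (10.2, 7.66 to 13.9) and 193 against 35 (3.64, 2.53 to 5.37). A 359-nt stretch had ratios of 3.24 (2.91 to 3.6) and 6.82 (5.25 to 9.0).

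**Figure D2:**
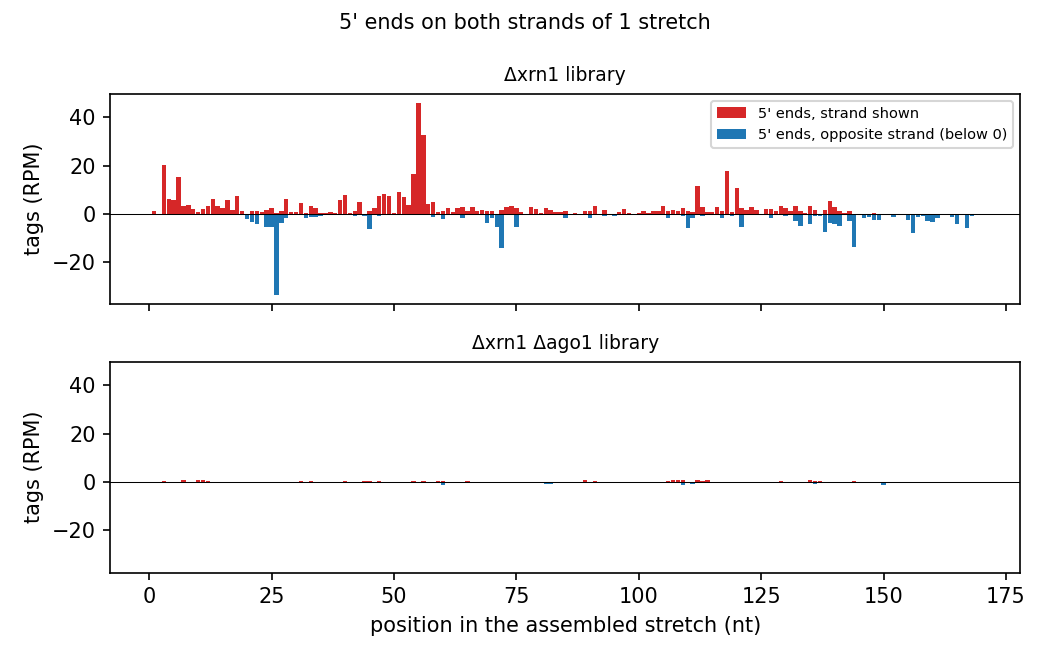
Bars are tags as RPM by the position (nt) of their 5' end in the 169-nt stretch, above 0 for the strand shown and below 0 for the opposite strand, in the Δxrn1 library (top) and the Δxrn1 Δago1 library (bottom), with tags that run past an end of the stretch not counted. The Δxrn1 library holds 1410 and 796 tags on the 2 strands and the Δxrn1 Δago1 library 40 and 42.

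The other 28 stretches had tags almost wholly on 1 strand and held 65 sites. Their ratios given here also include the enriched sites. The split of stretches is not that of sites: 9 of the 55 sites with opposite-strand tags lay in 1-strand stretches, and 13 of the 70 sites without them in 2-strand stretches. Of the 28 stretches, 2 were recognised as rRNA (18S and 25S), and 9 held a reading frame similar to a conserved segment of an abundant yeast protein. The other 5 among the 10 stretches richest in enriched-site tags were of this kind. A 62-nt stretch had 1242 tags against 16 (51.2, 31.4 to 89.8), a 164-nt stretch 1770 against 97 (12, 9.80 to 14.9) and a 133-nt stretch 1399 against 99 (9.32, 7.59 to 11.5). A 193-nt stretch with a protein-like frame had 1603 against 320, a ratio of 3.30 (2.93 to 3.74) that lay below that of inner rRNA, although 3 of its sites passed 10-fold. The remaining one was 18S rRNA, whose 283593 tags with AGO1 and 240531 without lay mostly at its mature end.

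A further question was whether the enriched sites held A at position 10. Argonaute cuts its target opposite guide nucleotides 10 and 11, so that the base paired to the first guide nucleotide becomes position 10 of the downstream piece, and budding-yeast small interfering RNAs mostly begin with U. Among all 202 AGO1-enriched sites, 50% had A there (42.9 to 57.1; matched lists' median 37.1%, 95% range 30.2 to 43.6). The share was as high, 53.7% (43.8 to 63.4), among all 108 Δago1-enriched sites. However, 88 of these 108 sites, and 64 of the 202, were error variants within 3 mismatches of a mature rRNA end. Such variants mostly keep the base of that end at position 10. The shares as counted, and their matched range, therefore cannot decide whether the directions differ at this position. Without error variants the share was 48.0% of 125 sites (39.0 to 57.1; matched 95% range 27.2 to 44.0), while the 10 Δago1-enriched sites, 5 with A, were too few to compare. The share was 60% in the 55 sites with opposite-strand tags (45.9 to 73.0; matched 95% range 23.6 to 49.1). It was 38.6% in the 70 sites without them (27.2 to 51.0; matched 95% range 24.3 to 47.1). The difference between these groups was not tested, and their intervals overlap. For A, position 10 was the only position of the 55 sites above its matched range, and position 1 was below it, with 16.4% A (7.77 to 28.8). Other bases were not set against matched lists. T at position 1 was also frequent, in 61.8% of the 55 sites against 26.4% of the 7141 sites not enriched, so position 10 was not their only difference in base content. Sites of 1 stretch are not independent of each other. Without the stretch of 18 sites, 24 of 37 sites had A at position 10 (64.9%, 47.5 to 79.8), and with 1 site per stretch, adjoining stretches joined, 10 of 14 did (71.4%, 41.9 to 91.6).

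**Figure D3:**
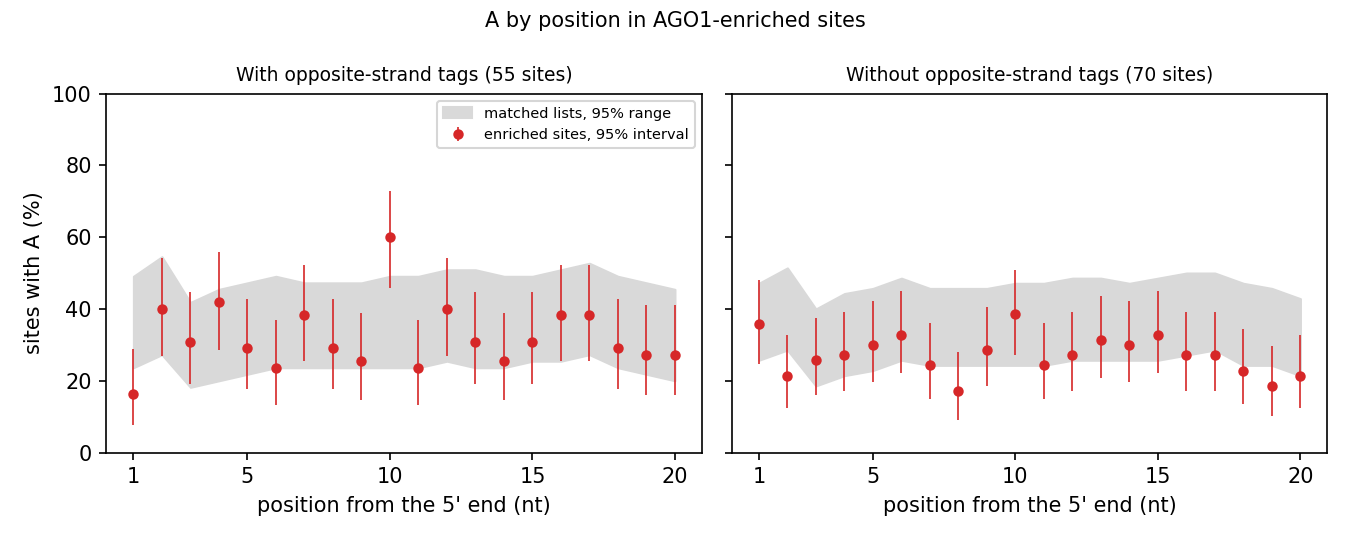
Points give the percent of AGO1-enriched sites with A at each position counted from the 5' end (nt), with exact 95% intervals, for 55 sites with (left) and 70 sites without (right) opposite-strand tags, and the grey band is the 95% range of 10000 matched lists. At position 10 the left panel shows 60%, above its band, and the right panel 38.6%, within its band.

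If both strands of a small RNA duplex guided cleavage, 5' ends of opposite strands would lie 1 or 2 nt apart. Among AGO1-enriched sites, 17 pairs on opposite strands of a stretch lay within 30 nt, and 0 of them were at an offset of 1 or 2 nt. At the mean of the other offsets, 0.576 pairs would be at these 2, so a preference was not detectable at this number of pairs. At 4-fold, 12 of 213 pairs had these offsets (4 at 1 nt and 8 at 2 nt), where the mean of the other offsets would give 6.81 at both together, and the highest value at any other single offset was 8.

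The deleted genes were checked only indirectly, since AGO1 and XRN1 were not located among the tags. Tags matching a hygromycin resistance gene, a common marker of yeast gene deletions, numbered 0 in the AGO1 library and 209 in the Δago1 library, or 99.6 RPM (86.6 to 114), at 65 positions. A count of 0 allows up to 0.943 RPM. Tags of a kanamycin resistance gene were in both libraries, 1585 with AGO1 and 789 without. Their ratio was 0.722 (0.644 to 0.810) at the start of the gene and 2.93 (2.53 to 3.41) further in. A nourseothricin resistance gene had 0 tags in both. The labels do not say which marker replaced which gene, so the hygromycin counts show only that the Δago1 library held a marker not detected in the AGO1 library. Within the kanamycin gene, the AGO1 library was lower at the start and higher further in. Inner 5' ends of this 1 RNA outside rRNA were thus also in excess in the AGO1 library, as in rRNA.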

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

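The test in this part was chosen after its result was seen. Resistance-gene tags lie outside the yeast genome and were not part of the main measurement. Hygromycin resistance tags numbered 209 in the Δago1 library and 0 in the AGO1 library. Kanamycin resistance tags numbered 1585 in the AGO1 library and 789 in the Δago1 library. All 3 nonzero counts were above the 3 tags that a count of 0 allows.

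An exchange of the libraries was weighed for the hygromycin tags. If the additional marker belongs to the strain with the additional deletion, an exchange would put its tags in the library labelled with AGO1, which had 0 against 209 in the other, and this argues against an exchange. The argument rests on the assumption that the marker stands for the AGO1 deletion, which the labels do not state. No tags of the AGO1 gene itself were located.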

How the results depend on the processing

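No paired analysis was possible because each genotype has 1 library. The fourth-column, adapter-mismatch and error variant alternatives were chosen after the data were seen. Alternatives that need a genome were not run (25-nt matches, 1 genome match, 1 mismatch to the genome), nor were counts of each distinct tag once. Median-of-ratios scaling (5195 sites) moved the log2 ratios of AGO1 over Δago1 up by 0.45 relative to tag totals. Scaling outside the recognised rRNA moved them by -0.11. In every setting run, more sites were higher in the AGO1 than in the Δago1 library once error variants were left out, but as counted this failed with 1 adapter mismatch allowed, with 352 against 375. Apart from the setting with the AGO1 library thinned to the other's depth, these counts come from libraries of unlike depth, so their cut-offs differ. The counts of AGO1-enriched sites, as counted and then without error variants (main 202 and 125), were 377 and 244 with median scaling, 80 and 32 with 21-nt tags only, 1082 and 754 at 4-fold, 56 and 35 at 20-fold, and 352 and 239 with an adapter mismatch. Merging 5' ends within 2 nt gave 216 without error variants. The Δago1-enriched counts (main 108 and 10) were 39 and 4 with 21-nt tags, 36 and 4 at 50 tags, 197 and 47 at 4-fold, 43 and 1 at 20-fold, and 375 and 20 with an adapter mismatch. They were 58 as counted with the fourth column, and without error variants 5 with median scaling and 6 with merging. The share with A at position 10 moved only at 4-fold, to 41.0% as counted and 38.2% without error variants. Opposite-strand pairs at 1 or 2 nt (main 0) numbered 4 with median scaling and 12 at 4-fold. An adapter mismatch raised the usable share to 38.8% with AGO1 and 33.3% without, and the inner rRNA ratio to 4.96. Hygromycin tags were 114 RPM with the fourth column (main 99.6) and stayed at 0 in the AGO1 library in all 3 read selections. For the moved values the cause was not tested, apart from the fewer or more sites that a stricter or looser threshold passes by construction. Depth limited the ratios, since the floor of 3 tags equals 1.43 RPM without AGO1. The share with A among sites with opposite-strand tags stayed within its interval without the stretch of 18 sites and with 1 site per joined stretch.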

Other observations

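All tests in this part were chosen after results on these data had been seen, except the one on depth. Position 10 was fixed before the data were examined, but its share without error variants was known before the split by strand was made.

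Sites without opposite-strand tags differed from the others in how they began. Of 70 such sites 13 began with AGG (18.6%, 10.3 to 29.7), against 0 of 55 with opposite-strand tags (upper bound 6.49%) and 205 of 7141 sites not enriched (2.87%, 2.5 to 3.28). A 51-nt stretch, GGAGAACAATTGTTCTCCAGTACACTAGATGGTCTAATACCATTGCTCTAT, which begins with an 18-nt palindrome, had 1446 tags without AGO1 and 225 with it, 9.75-fold more in the Δago1 library (8.47 to 11.3).

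The first pattern is the excess of AGO1-enriched sites, above all those with tags on both strands. Lower depth of the Δago1 library is argued against, since 126 sites passed in the AGO1 library after it was thinned to equal depth, against 9 in the other. Slicing guided by small RNAs that begin with U is a candidate explanation for sites with opposite-strand tags, 60% of which had A at position 10, above the matched lists' upper bound of 49.1%. Those lists drew sites independently and were compared for A only. With 1 site per joined stretch (10 of 14 with A), the interval of 41.9 to 91.6 spans that bound. A general excess of inner RNA fragments was weighed on the tags of the 13 2-strand stretches outside the enriched sites, whose median ratio was 10.1. The lower bound lay above the 95th percentile of inner rRNA sites (8.73) in 6 stretches, or 5 of 12 with adjoining ones joined, which argues against an excess of that size as their whole cause, while it stays open for the other 7 and for an excess that differs between RNAs. This limit was set after the values were known: an earlier one, a larger share of stretches with a ratio above 8.73, had left the explanation open, and a looser one, the highest upper bound of an assembled rRNA part (5.67, from the 27 and 8 tags of 5.8S), was passed by 9 stretches.

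The second pattern is the sites without opposite-strand tags, 56 of 70 of which lay in 1-strand stretches. The tests on 1-strand stretches also cover 9 sites that had such tags. A general excess of inner fragments stays open for the 9 stretches with a protein-like frame: their tags outside the enriched sites had a median ratio of 3.18, which does not show why the sites themselves passed 10-fold. Another 17 stretches had no similarity to the protein segments compared, and 1 of them adjoined a protein-like one. They can still hold coding sequence, so they are not a contrast to the protein-like ones. Of these 17, 2 had under 20 tags outside the enriched sites, and 3 of the other 15 had a lower bound above 8.73. Slicing cannot be told apart from other sources here, since 38.6% of the 70 sites had A at position 10 and the interval, 27.2 to 51.0, spans the matched upper bound of 47.1%. Of the 28 stretches, 25 had, with any adjoining stretch, over 3 tags in the strain lacking AGO1. This argues against tags of the deleted AGO1 gene for them, with 1 exception. The exception, 46 nt long with 431 tags against 0, is counted only through 14 nt shared with a stretch of 168 against 4. Tags of the deleted gene stay open for this stretch and for the 3 with at most 3 tags. A difference between the strains' cultures or library preparations was not tested and is confounded with genotype.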
